A study of Mus musculus with 3 samples.

How the data were processed

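Polyadenylated RNA was sequenced from regulatory T cells of mouse, in 3 libraries that the labels describe as technical replicates 1, 2 and 3 of biological replicate 1. The cells came from a male adult of 4 months that carried a Foxp3CreERT2 allele and a Rosa26YFP reporter, per the labels. All 3 libraries form 1 group, so no comparison between conditions exists. Libraries are named here by their technical replicate number.

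The authors deposited 4 tables for each library. The gene table gives expected counts, TPM and FPKM per gene, made from an alignment to the transcriptome of mouse genome build mm10 with the GENCODE M21 annotation, per the deposited readme of each library. A transcript table from the same alignment holds expected counts, TPM and the percent of the gene's TPM that each transcript takes, per the file headers. A second transcript table holds estimated counts and TPM made from the reads and a transcript index of the same annotation, per the deposited readme. A further gene table holds whole-number counts per gene for the GENCODE M4 annotation of mm10, per the deposited readme, and its unit was read from its values. The names and versions of the aligner, quantifiers and counter are not given in the sources used here. The column names of the first tables are those that RSEM writes, and those of the second transcript table are those that kallisto writes. Whether the counting used strand is not given in the sources used here.

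The gene table with expected counts was the main source. All 55536 mouse genes in it matched the GENCODE M21 reference by identifier, which gave symbols, gene types and mm10 coordinates, and 99.8% of them had a GC value. The 26248 tRNA-like entries, 96 ERCC spike-in sequences and the phiX174 genome listed in the same table were left out of library totals and tests. They held 0.117%, 0.124% and 0.135% of the counts of libraries 1, 2 and 3. Where a symbol had more than 1 identifier, the one with the higher mean TPM was used. Genes that share sequence with near-identical copies, such as Hba-a1 and Hba-a2, ribosomal protein pseudogenes or V segments of 1 family, have uncertain counts, as do overlapping genes.

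A gene was called detected at 1 TPM or more in every library. Expected counts were rounded to whole numbers for count tests. For each gene with 30 or more counts over the libraries, a chi-square test of homogeneity compared its counts with the TMM-scaled library totals (edgeR 4.0.16 in R 4.3.3), with Benjamini-Hochberg adjustment and a threshold of 0.05. The coefficient of variation among libraries is the square root of the common dispersion of edgeR from a fit with an intercept only. Values are given as mean ± SD over the 3 libraries. Spread and p-values measure only the spread between these 3 libraries, which per the labels is technical, and the tests compare the libraries, not conditions. Whether the libraries came from 1 pool of RNA, from separate sorts or from separate animals is not given in the sources used here.

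For each of 31 gene lists, the members detected were counted, and the median of log2(TPM + 1) was placed as a percentile among 10000 random lists of the same size drawn from protein-coding genes. The spread of a list was described by its median chi-square value per degree of freedom, placed among 10000 random lists matched on counts in 20 bins. These percentiles describe the libraries and are not p-values. V segment use was compared between libraries by a chi-square test of homogeneity and by Cramér's V. Counting error alone raises Cramér's V above 0, by an amount that depends on the numbers of segments and counts, and this amount was computed from the degrees of freedom. The M4 counts were matched to the main table by identifier without its version, scaled to CPM (counts scaled to the library total) over the shared genes and centred on the median ratio. A gene was called different when it differed by more than 2-fold in the same direction in all 3 libraries, among genes at 1 or more CPM in both tables. The share of a transcript is its percent of the TPM of its gene. These calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

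Intervals are 95% intervals, by the method of Wilson for shares and by the exact binomial method for ratios of counts. They cover counting error only, because PCR reads without molecular identifiers are not independent molecules. The limit that a count of 0 allows was set at 3 counts of the total.

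The spread test was checked on 3 simulated libraries with Poisson noise and the real means and library sizes, over 12939 genes. It called 9 of 12740 unchanged genes, 70 of 99 genes raised 1.5-fold in library 1 and 79 of 100 genes raised 2-fold. The simulated counts had counting noise only, which the test assumes. The check therefore does not give the rate of false calls in the real counts, whose reads are not independent molecules.

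The gene lists, the tests of detection, spread, Trbv use, gene tables and transcripts, their thresholds and the rule for the genes named in the text were fixed before the data were examined. The trends with gene length, GC content and coding share and the comparison of Igkv and Ighv segments were added later. The rule takes 20 genes of regulatory and other T cells that are always named, up to 4 members with the highest and up to 2 with the lowest mean TPM of each list, and the 10 protein-coding genes with the highest mean TPM. It adds the 10 genes with the largest ratio between the highest and lowest scaled library among varying genes with 300 or more counts in all, with a floor of 3 counts for the lowest library that was added to the rule after the data were seen. The 10 largest differences between the gene tables and the 3 most used Trbv segments complete it. Alternatives were other detection thresholds, FPKM, posterior mean estimates, other scalings (among them size factors of DESeq2 1.42.0) and count filters, other gene sets, another transcript table, and leaving out each library. Scaling within 20 bins of gene length or GC content, and the second transcript table summed per gene, were added after the data were seen. Pairs of libraries were scaled within the same kinds of bins, with 20 resamples of genes for the spread of the coefficient of variation. Of the listed symbols, 5 older ones had no entry under that symbol in the annotation and were left out.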

Results

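Gene expression was measured by sequencing polyadenylated RNA of regulatory T cells, the CD4 T cells that restrain immune responses and are defined by the transcription factor Foxp3. Per the labels, the cells came from 1 adult male mouse sample, and 3 libraries were made from it as technical replicates. The gene totals were 9299054, 9188612 and 8284381 expected counts in libraries 1, 2 and 3. Protein-coding genes took 93.0% ± 0.385 (SD, n = 3) of them, mitochondrial genes 3.35% ± 0.609 and ribosomal protein genes 5.59% ± 1.07. In every library 12183 genes reached 1 TPM, among them 10120 of 22028 protein-coding genes. The highest protein-coding genes were the cytoskeletal gene Actb at 15201 ± 2762 TPM, the ribosomal gene Rps19 at 10460.0 ± 1371 TPM and the mitochondrial gene mt-Co3 at 10230.4 ± 1717 TPM. With posterior mean TPM in place of TPM, the number of detected genes was 20313, more than the 20217 genes with any expected count in library 3.

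The first question was which cell identity and activation genes these libraries express. The 17 genes of the regulatory T cell list were all detected. They were led by Izumo1r, the folate receptor 4 of regulatory T cells, at 1313 ± 123 TPM (SD, n = 3), and by the costimulatory receptors Tnfrsf4 at 1074 ± 45.8 and Tnfrsf18 at 689 ± 62.7 TPM. Ikzf2, which encodes Helios, stood at 425 ± 37.1 TPM, the interleukin-2 receptor chain Il2ra at 304 ± 83.0 and the inhibitory receptor Ctla4 at 217 ± 11.6. Foxp3 itself (ENSMUSG00000039521.13, mm10 chromosome X, 7573644 to 7595245) had 39.4 ± 10.4 TPM, from 345, 464 and 450 counts in libraries 1, 2 and 3. The lowest members were Plagl1 at 2.35 ± 0.709 and Socs2 at 26.8 ± 6.65 TPM. The median of the list lay at percentile 100 of random lists of protein-coding genes, as did that of the 18 pan T cell genes, all detected, with Trbc2 at 3978 ± 474, Trac at 2859 ± 288, Lck at 1566 ± 134, Cd3e at 1398 ± 50.5 and Cd4 at 455 ± 82.0 TPM. Of the 16 genes of suppressive mediators 14 were detected, with Tigit at 343 ± 73.6, Lgals1 at 328 ± 54.1 and Pdcd1 at 227 ± 36.4 TPM. The cytokine Il10 had 7.87 ± 2.90 TPM, and Il12a and Areg had 0.967 ± 0.496 and 1.24 ± 0.867 TPM. All 18 genes of the list of Foxp3 partners were detected, from Ets1 at 716 ± 177 to Foxo3 at 6.47 ± 0.922 TPM.

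**Figure D1:**
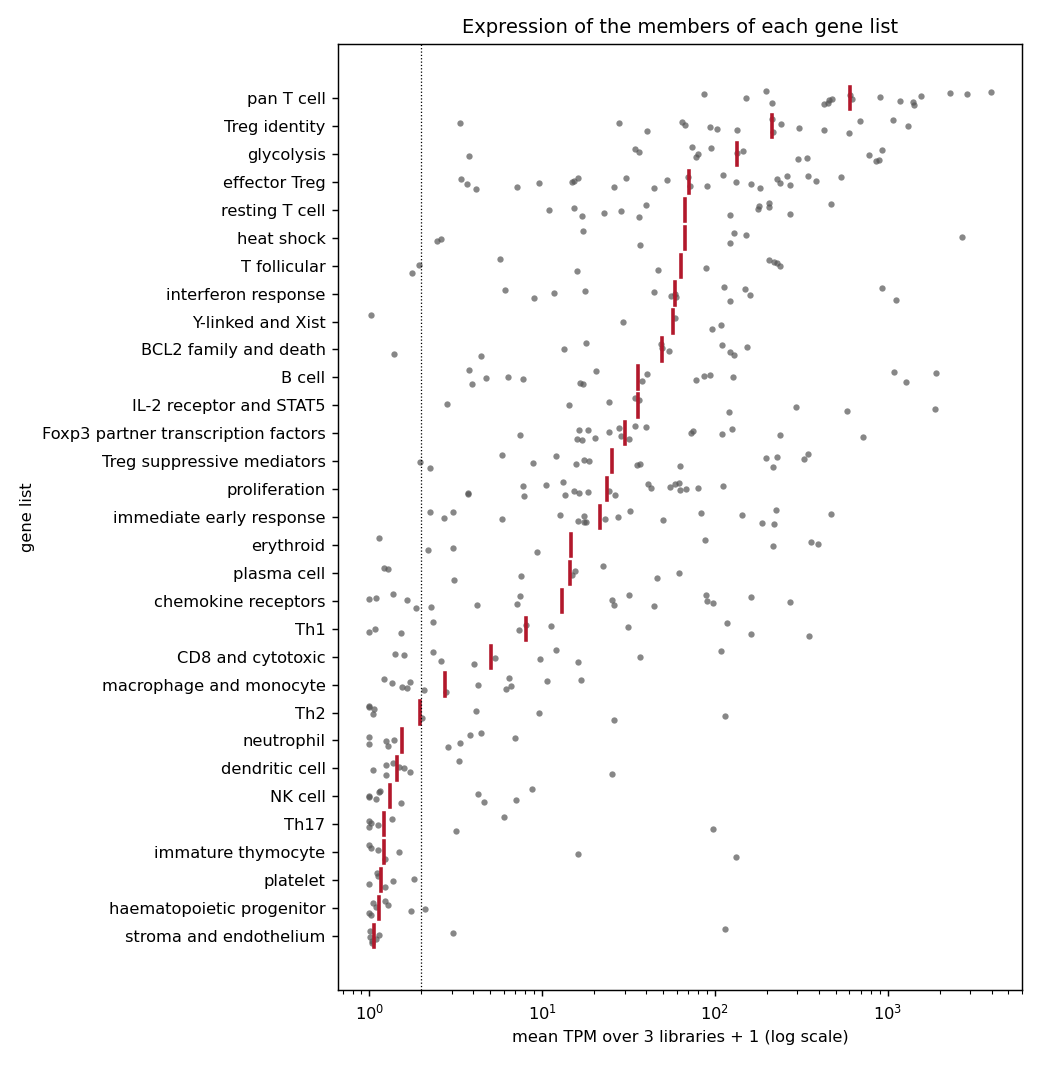
Members of the 31 gene lists. Each point is a gene at its mean TPM over the 3 libraries plus 1 (log scale), the red bar is the median of the list and the dotted line marks 1 TPM. The pan T cell and regulatory T cell lists lie highest, and the lists of progenitors, platelets and stroma lie at the bottom, with Pecam1 at 114 TPM as the one high stromal list member.

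Genes of both resting and effector cells were expressed. All 14 genes of the resting T cell list were detected, with the lymph node homing receptor Ccr7 at 270.2 ± 29.6 TPM and the transcription factors Lef1 and Tcf7 at 205 ± 22.0 and 205 ± 17.1 TPM. Il7r had 177 ± 46.9 TPM, while Klf2 and Igfbp4 were the lowest of the list. Klf2 had 14.4 ± 1.87 TPM, and Igfbp4 had 4.78, 9.91 and 15.3 TPM in libraries 1, 2 and 3. All 26 genes of the effector regulatory T cell list were detected too, with S100a11 at 537 ± 122, Ly6a at 382 ± 54.3, Cd83 at 272 ± 30.1, Klrg1 at 131 ± 19.9 and Cd44 at 71.1 ± 7.93 TPM, down to Nfil3 at 2.41 ± 0.50 and Havcr2 at 2.70 ± 0.783 TPM. Each of these lists had its median at percentile 100. The 21 proliferation genes were all detected at percentile 99.9 (65.3 against random lists of detected protein-coding genes), with the replication genes Pcna at 111 ± 9.59 and Mcm6 at 79.2 ± 10.4 TPM as the highest members and the mitotic genes Bub1 and Ccna2 as the lowest. Mki67 stood at 6.75 ± 1.47, Bub1 at 2.72 ± 1.17 and Ccna2 at 2.71 ± 0.415 TPM.

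Lists of signalling and metabolism lay high among random lists of all protein-coding genes, and several of them did not among random lists of detected genes. All 9 genes of the interleukin-2 receptor list were detected (percentile 99.2), with the common chain Il2rg at 1871 ± 11.2, Il2rb at 581 ± 146 and Jak1 at 293 ± 83.4 TPM, and the feedback inhibitors Cish at 119 ± 15.8 and Socs1 at 1.81 ± 0.462 TPM. All 14 interferon response genes were detected (percentile 100), with Ifi27l2a at 1113 ± 169 and Irf7 at 158 ± 29.1 TPM. The immediate early list had 17 of 19 members detected (percentile 99.7), led by Nfkbia at 469.8 ± 77.8 and Zfp36 at 223 ± 42.9 TPM, with Fosb at 1.69 ± 0.697 and Nr4a3 at 1.26 ± 0.499 at its lower end. All 15 glycolysis genes were detected (percentile 100), led by Pkm at 927 ± 76.5 TPM and Eno1 at 895 ± 39.2 TPM, with Hk2 lowest at 2.79 ± 0.555. The heat shock list had 6 of 8 members detected (percentile 99.9), with Hspa8 at 2692 ± 400.4 TPM, and the list of cell death genes had 10 of 11 (percentile 99.9), with Casp8 at 152 ± 9.16, Bcl2 at 121 ± 34.2 and Bbc3 at 0.393 ± 0.190 TPM. Of 18 chemokine receptors 12 were detected (percentile 97.8), led by Ccr7, then Cxcr3 at 161 ± 18.3, Ccr6 at 96.9 ± 4.42 and Ccr8 at 88.6 ± 7.11 TPM, while Cxcr1 was at 0 in each library. In all, 17 of the 31 lists had a median above percentile 95, while 8 had one against random lists of detected protein-coding genes. Those 8 were the regulatory T cell, pan T cell, resting, effector, T follicular, heat shock, interferon response and glycolysis lists. Against such lists the B cell list lay at percentile 90.5, Y-linked genes at 90.5, cell death at 94.3, Foxp3 partners at 82.2, the interleukin-2 receptor list at 82.2, suppressive mediators at 68.4, immediate early genes at 53.6 and chemokine receptors at 12.1.

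Genes that define other T helper cells were mixed. Of 11 Th1 genes 8 were detected (percentile 85.5), among them Ccl5 at 348 ± 75.0 and Stat4 at 116 ± 4.01 TPM, while the Th1 regulator Tbx21 had 1.35 ± 0.341 TPM. Of 9 Th2 genes 4 were detected (percentile 54.1), with the transcription factor Gata3 at 113 ± 13.9 TPM, Il4 at 3.12 ± 0.350 and Il9 at 0 in each library. Of 8 Th17 genes 3 were detected (percentile 29.9), with the chemokine receptor Ccr6 high and Il17a and Il22 at 0 in each library. The T follicular list had 8 of 10 members detected (percentile 99.96), with Icos at 237 ± 6.84 TPM, Sh2d1a at 219 ± 32.4, Bcl6 at 14.9 ± 3.5 and Il21 at 0.940 ± 0.370 TPM. Of 11 genes of CD8 and cytotoxic cells 7 were detected (percentile 75.7), with Nkg7 at 107 ± 9.93, Gzmb at 35.8 ± 9.38, Cd8b1 at 15.1 ± 2.05 and Cd8a at 3.06 ± 1.54 TPM. The immature thymocyte list had 2 of 7 detected (percentile 38.6), namely Cd1d1 at 131 ± 8.67 TPM and Cd8b1, which the CD8 list holds too. Rag1 had 0.0200 ± 0.0346 TPM. The Y-linked genes Eif2s3y and Ddx3y had 107 ± 20.3 and 94.8 ± 27.1 TPM and Xist 0.0167 ± 0.0208 TPM, for a sample labelled male.

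Markers of other blood cells were partly present. All 17 B cell genes were detected (percentile 100), with Ighm at 1892 ± 260, Cd74 at 1272 ± 273 and H2-Aa at 126 ± 50.1 TPM, while the B cell transcription factor Pax5 had 2.79 ± 1.49 TPM. The erythroid list had 3 of 8 detected and the plasma cell list 6 of 9 (percentiles 93.5 and 93.1). Without library 2, 6 erythroid genes were detected, at percentile 99.5. Of 13 macrophage and monocyte genes 7 were detected (percentile 62.6), with Lyz2 highest at 15.9 ± 8.45 TPM. Of 10 NK cell genes 4 were detected (percentile 35.5), with Tyrobp at 7.70 ± 4.69 TPM, and of 9 dendritic cell genes 2 (percentile 44.4), led by Ccr9 at 24.2 ± 9.45 TPM, a receptor that the chemokine receptor list holds too. None of the 10 neutrophil genes, 6 platelet genes or 8 progenitor genes reached 1 TPM in every library (percentiles 41.9, 26.7 and 25.2), though 1 neutrophil gene did without library 2 and 1 progenitor gene without library 1. Of 8 stromal and endothelial genes 2 did (percentile 18.7), Pecam1 at 114 ± 24.0 and Epcam at 2.06 ± 1.24 TPM. The source label gives bone marrow haematopoietic cells as origin, and the progenitor gene Kit had 1.1 ± 0.663 TPM and Gata2 was at 0 in each library.

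The second question was how far the 3 libraries of this sample differed. Among varying genes with 300 or more counts, the 10 with the largest ratios between libraries included 4 globin genes and 2 immunoglobulin kappa V segments. The globin genes Hba-a2 (mm10 chromosome 11, 32296489 to 32297298), Hbb-bs (chromosome 7, 103826534 to 103828096), Hba-a1 and Hbb-bt had 584, 603, 344 and 137 TPM in library 1, and 599.5, 464, 297 and 122 TPM in library 3. In library 2 they had 0.830, 2.66, 3.59 and 0.440 TPM. Their summed counts were 5466, 18 and 3751 in libraries 1, 2 and 3, or 0.0588% (95% Wilson interval 0.0572 to 0.0604), 0.000196% (0.000124 to 0.000310) and 0.0453% (0.0439 to 0.0468) of the total. Scaled by library size, library 1 had 327 times the globin counts of library 2 (exact interval 207 to 552) and 1.39 times those of library 3 (1.33 to 1.45). For Hba-a2, whose TPM was lower in library 1 than in library 3, the scaled count ratio was 1.21 (1.13 to 1.30). Alas2, an enzyme of haem synthesis in red cell precursors that lies outside the naming rule and was chosen after its values were seen, had 145, 4 and 118 counts.

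Plasma cell genes followed the same order of libraries in part. The immunoglobulin light chain gene Igkc (chromosome 6, 70726435 to 70726966) had 1842, 201 and 1203 TPM in libraries 1, 2 and 3, the joining chain Jchain 98.5, 4.42 and 79.7 TPM, and the antibody heavy chain Igha 36.4, 1.35 and 98.5 TPM. Xbp1, a transcription factor of antibody-secreting cells, went another way with 8.2, 30.7 and 26.0 TPM. Ighm differed less, 1.59-fold between libraries 1 and 2 (exact interval 1.56 to 1.62). The neutrophil granule gene Ngp had 17.6 TPM in library 1, from 149 counts, against 0 and 1 counts in libraries 2 and 3. The other 4 of the 10 genes with the largest ratios were the pseudogenes Gm10163 (0.490, 58.0 and 319 TPM) and Rpl7a-ps11 (41.7, 0.460 and 38.0 TPM), Gm45837 (11.2, 0.0300 and 23.3 TPM) and the noncoding Gm26699 (18.6, 0 and 0.410 TPM), whose reads can belong to copies or overlapping genes.

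**Figure D2:**
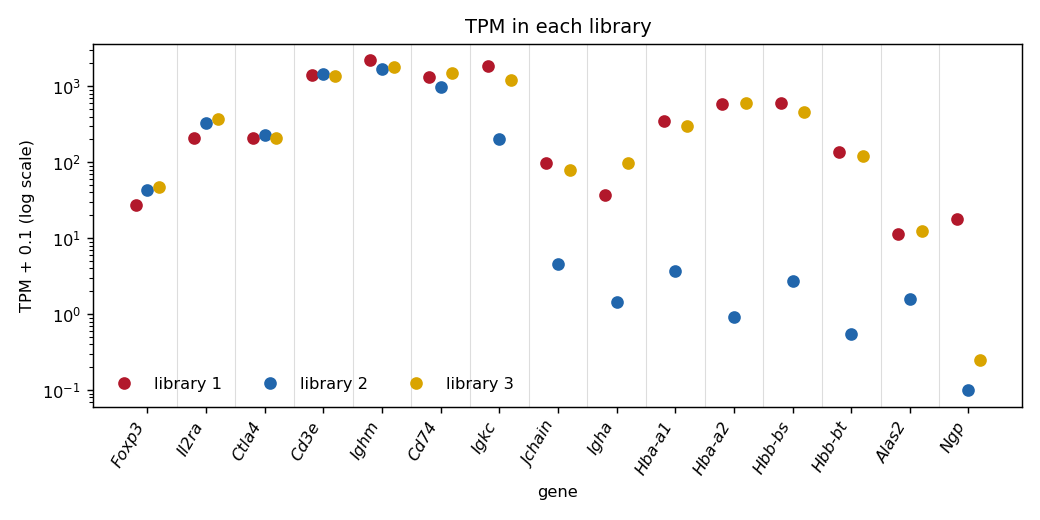
TPM of 15 genes in each library, plotted as TPM plus 0.1 on a log scale, with 1 point per library. Foxp3, Il2ra, Ctla4 and Cd3e lie close together, while the globin genes, Alas2, Jchain and Igha lie lowest in library 2 and Ngp is highest in library 1 at 17.6 TPM.

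Over all genes, 7099 of 13071 tested differed between libraries by the chi-square test, and 1150 of these by 2-fold or more. The coefficient of variation among libraries was 20.2%. Library 1 stood apart. Without it, 2142 genes differed and the coefficient of variation was 12.4%, whereas 5699 genes differed between libraries 1 and 2 and 5980 between libraries 1 and 3. Mitochondrial genes took 4.05% of the counts of library 1 (95% Wilson interval 4.04 to 4.07) against 3.05% (3.04 to 3.06) and 2.95% (2.94 to 2.96) of those of libraries 2 and 3. Ribosomal protein genes took 6.82% (6.80 to 6.84) against 4.84% (4.82 to 4.85) and 5.12% (5.11 to 5.14). The difference followed gene length, a trend examined after the data were seen. In the shortest decile of protein-coding genes (median length 825 bases) library 1 lay 0.36 above the mean of the libraries on the log2 scale, and in the longest decile (5682 bases) at -0.22. Libraries 2 and 3 ran from -0.16 and -0.18 to 0.07 and 0.15. Across 7872 genes, which are not independent replicates, the Spearman correlation of the deviation with length was -0.672 in library 1, 0.472 in library 2 and 0.579 in library 3. With GC content it was -0.0247, 0.163 and -0.103 in libraries 1, 2 and 3. Deviations from the mean of the 3 libraries sum to 0 for each gene, so the trends of the libraries are not independent results. Between libraries 2 and 3 alone, scaling within length bins changed the coefficient of variation only from 12.4% to 12.2%. After scaling within bins of gene length, a step added after the data were seen, 5835 genes differed.

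**Figure D3:**
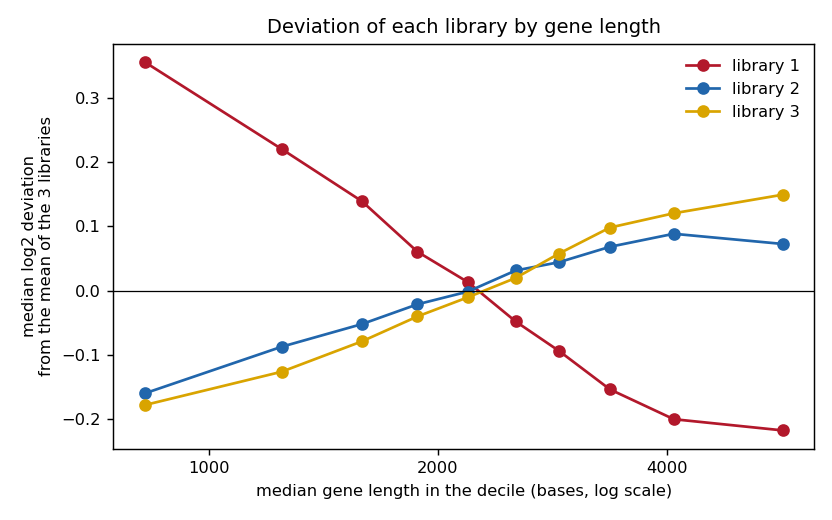
Median log2 deviation of each library from the mean of the 3 libraries, over deciles of gene length in bases (log scale), for protein-coding genes with 300 or more counts. Library 1 falls from 0.36 in the shortest decile to -0.22 in the longest, and libraries 2 and 3 rise. Deviations sum to 0 for each gene, so the 3 lines are not independent.

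Among the lists that could be tested, 8 had a spread above percentile 95 of lists matched on counts. They were the erythroid, plasma cell and B cell lists (each at percentile 100), suppressive mediators (99.6), heat shock (98.7), effector regulatory T cells (98.3), macrophage and monocyte (97.2) and chemokine receptors (95.9). B cell genes were lowest in library 2, with a median log2 ratio of -0.71 to the other libraries, and higher in library 3 at 0.69. Without library 2, and likewise without library 3, 5 lists had a spread above percentile 95. Within the effector list, Tigit had 408, 357 and 263 TPM in libraries 1, 2 and 3 and S100a11 676, 484 and 450.0 TPM. With scaling within length bins the effector list stayed at percentile 99.7, the CD8 and cytotoxic list lay at 96.7, and the lists of suppressive mediators and chemokine receptors lay at 87.3 and 94.8. The regulatory T cell list was at percentile 80.6, with 16 of 17 members past the test. Foxp3 had 27.6, 43.7 and 47.1 TPM and Il2ra 211, 332 and 369 TPM in libraries 1, 2 and 3. The test used scaled counts, in which both genes fell less in library 1 than in TPM. Library 1 had 0.731 (exact interval 0.633 to 0.842) and 0.742 (0.717 to 0.769) times the scaled counts of library 3 for Foxp3 and Il2ra. Against library 2 the exact intervals were 0.692 to 0.919 for Foxp3 and 0.887 to 0.952 for Il2ra. The remaining lists lay lower, among them pan T cell at 94.4, CD8 and cytotoxic cells at 92.7, NK cell at 91.6, cell death at 86.2, Y-linked genes at 78.0, glycolysis at 77.0, Th2 at 77.0, immediate early at 75.9, dendritic cell at 74.6, interleukin-2 receptor at 69.2, Th1 at 55.9, interferon response at 46.7, T follicular at 25.8, proliferation at 16.4, and resting T cells and Foxp3 partners at 4.41 each. The low values depended on the scaling, since with length bins Foxp3 partners lay at 62.7, T follicular at 62.7, proliferation at 61.6 and resting T cells at 38.4. Th1 then lay at 89.7 and glycolysis at 33.6. The Th17, neutrophil, platelet, progenitor, stromal and thymocyte lists had too few members with 30 counts.

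The use of T cell receptor beta V segments was close in the 3 libraries, from 5712, 4437 and 3632 Trbv counts. Trbv3 took 10.9% ± 0.470 (SD, n = 3) of the counts, Trbv19 9.40% ± 0.949 and Trbv13-2 9.16% ± 0.766, and the 5 highest segments of library 1 held 44.5%, 42.2% and 43.0% of the Trbv counts of libraries 1, 2 and 3. The composition differed beyond counting error by a chi-square test of homogeneity (chi-square 145 on 48 degrees of freedom, p = 1.03e-11), with a Cramér's V of 0.0726, where counting error alone gives about 0.0417. The immunoglobulin kappa V segments, compared after the data were seen, gave another picture. Their counts were 2040, 135 and 945, and Cramér's V was 0.681 over the 3 libraries, where counting error alone gives about 0.156. Between libraries 1 and 3 the chi-square value per degree of freedom was 22.6 for Igkv and 2.77 for Trbv. Igkv8-30 took 20.9% of the Igkv counts of library 1 (95% Wilson interval 19.2 to 22.8) and 0.741% of those of library 3 (0.359 to 1.52). Igkv19-93 took 15.3% (13.8 to 16.9) and 0.423% (0.165 to 1.08). Igkv5-39, chosen after its values were seen, took 1.67% (1.2 to 2.32) and 16.4% (14.2 to 18.9). The 5 highest Igkv segments of library 1 held 66.7% of its Igkv counts (64.6 to 68.7) and 15.2% of those of library 3 (13.1 to 17.7).

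**Figure D4:**
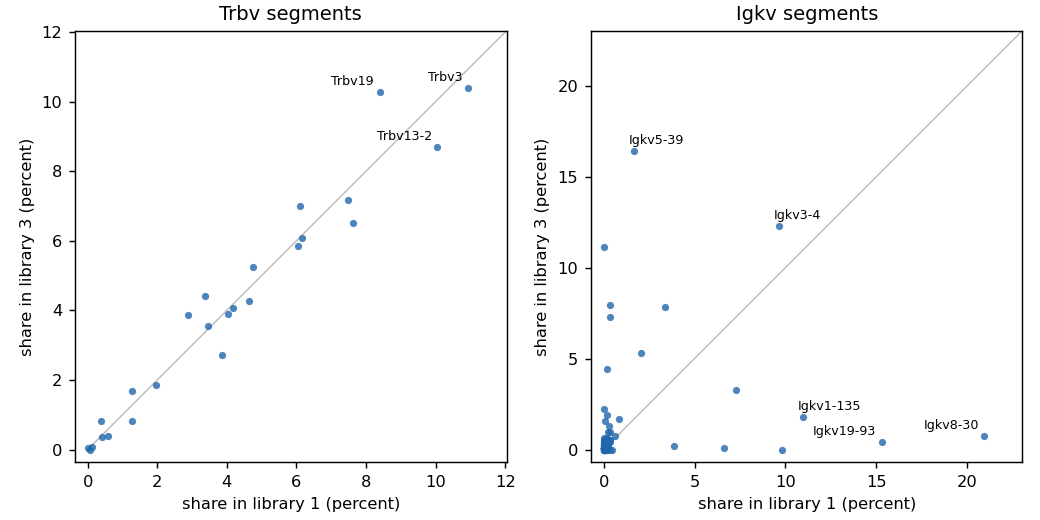
Share of each Trbv segment (left) and Igkv segment (right) among the V counts of library 1 and of library 3, in percent, with 1 point per segment and the line of equal shares. Trbv segments lie near the line, with Trbv3 at 10.9% and 10.4%, while Igkv8-30 and Igkv5-39 lie far from it on either side.

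The third question was whether the deposited gene tables gave the same picture. Ikzf2, Ets1 and Il2ra had more than 2-fold fewer counts in the M4 table than in the M21 table, while Foxp3, Ctla4 and Gata3 differed by less than 2-fold. On the log2 scale, M4 over M21 after centring was -2.66 ± 0.12 (SD, n = 3) for Ikzf2, -3.48 ± 0.51 for Ets1 and -1.21 ± 0.06 for Il2ra, against 0.65 ± 0.04 for Foxp3, -0.49 ± 0.02 for Ctla4 and -0.17 ± 0.02 for Gata3. Of 10091 genes at 1 or more CPM in both tables, 1271 were more than 2-fold lower and 118 more than 2-fold higher in the M4 table in all 3 libraries. The largest differences were Ube2h at -7.31 ± 0.36, Tmem127 at -7.18 ± 0.75, Klf13 at -6.77 ± 0.18, Gm11808 at -6.50 ± 0.36, Lars2 at -6.31 ± 0.65, Srsf2 at -6.27 ± 0.25, Sap18b at -6.00 ± 0.29, Atxn1 at -5.96 ± 0.89, Purb at -5.94 ± 0.48 and Ppp1r16b at -5.89 ± 0.23. Klf13, for example, had 6935, 7161 and 6544 expected counts in libraries 1, 2 and 3 in the M21 table and 81, 86 and 64 counts in the M4 table. The ratio followed the coding share of the exons, a relation examined after the data were seen, from a median of -0.85 in the decile with the lowest coding share (median 11.7% coding) to 0.59 in that with the highest (73.7% coding). With a limit of 1.5-fold in place of 2-fold, 3132 genes differed.

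**Figure D5:**
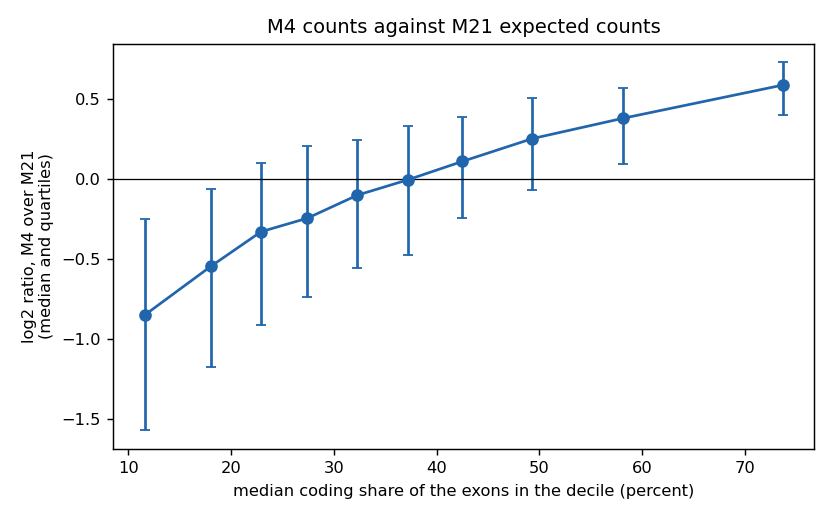
Median log2 ratio of M4 to M21 CPM (counts scaled to the library total), with bars from the lower to the upper quartile of genes, over deciles of the percent of exon bases that code for protein. The median rises from -0.85 to 0.59 across the deciles.

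The transcript tables were used for the 20 always-named genes. Foxp3 was assigned mainly to the transcript Foxp3-207, which the annotation classes as subject to nonsense-mediated decay, at 69.2% ± 5.33 (SD, n = 3) of the TPM of the gene. Per the labels the mouse carried a Foxp3CreERT2 allele. Whether that allele alters the assignment of reads to Foxp3 transcripts, or the TPM of Foxp3, was not tested. Transcripts with a retained intron led for Ikzf2 (Ikzf2-205, 63.9% ± 2.90) and Cd8a (Cd8a-203, 68.5% ± 8.16), and protein-coding transcripts led for the other 17 genes. Ctla4-201 took 97.9% ± 2.23, Gata3-201 98.9% ± 0.158, Il2ra-201 71.3% ± 5.63 and Cd44-207 49.3% ± 2.71 of their genes, and the leading transcript of Ptprc, Ptprc-203, 40.6% ± 1.21. The median share over the 20 genes was 85.2%. The second transcript table named the same leading transcript for all 20 genes, with a median share of 79.2%, and a lower share for Tnfrsf18-202 (53.2% ± 3.40 against 81.3% ± 2.41). A share of TPM weighs short transcripts more than a share of reads, and Ikzf2-205 held 28.6% of the estimated counts of Ikzf2 in that table.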

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

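The tests in this part were chosen after the result was seen, except the length-bin test of the globin genes, which was written after the globin difference but before its own value was seen. Reads of the phiX174 genome, a sequencing control outside the gene analysis, lay above the 3 counts taken as the limit of a count of 0, with 10907, 11349 and 11206 counts in libraries 1, 2 and 3. The spike-in sequences of the ERCC set had 0 counts in each library, which allows a share of up to 3.22e-05%, 3.26e-05% and 3.62e-05%.

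The second transcript table gave the pseudogene Gm29013 (mm10 chromosome 1, 105244425 to 105244661) 443984, 251527 and 235792 estimated counts in libraries 1, 2 and 3, or 26.1%, 19.1% and 19.6% of all TPM, where the main gene table gave it 0 expected counts in each library. Its transcript of 237 bases holds a run of 35 A, and among 210 transcripts with a run of 31 or more A or T it had the smallest effective length, 82.4 bases.

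Globin and immunoglobulin transcripts differed between libraries labelled as technical replicates of 1 sample. The tables argue against the length trend by its size. In the shortest decile, where it was largest, libraries 1 and 2 lay at 0.36 and -0.16 on the log2 scale. The globin ratio of library 1 to library 2 was 226 after scaling within length bins. That scaling moves a gene only by the median of its bin, so it could not have removed most of the ratio. RNA of red cells or their precursors in libraries 1 and 3 remains a candidate explanation, as all 4 globin genes were higher there and Alas2 counts were 36.2 times those of library 2 (exact interval 14.0 to 134). RNA of antibody-secreting cells could account for Igkc, Jchain and the unlike Igkv segments, and Mzb1 was higher in libraries 1 and 3 as well, at 3.81 (exact interval 2.57 to 5.80) and 2.09 (1.35 to 3.29) times library 2. Xbp1 in library 1 was 0.362 times that of library 2, which keeps it open. B cells express some of these genes too, 1 of 9 members of the plasma cell list is in another list (0 of 8 for the erythroid list), and the labels name no sorting gate. Separate sorts, aliquots or animals, and reads from other libraries sequenced alongside, were not tested, so whether the libraries share 1 pool of RNA stays open. With 1 group, no biological explanation was tested beyond RNA of red cells and of antibody-secreting cells.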

How the results depend on the processing

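The scalings within length or GC bins and the second transcript table summed per gene were added after the data were seen. The number of detected genes lay within 1.5 times of 12183 under every alternative but posterior mean TPM, with 20313. Its range without replicate 1, 2 or 3 was 12473 to 12876. Leaving out a library cannot lower this number, because detection asks for 1 TPM in every library used. The lists above percentile 95 numbered 17 or 18 (the range when a library was left out) except against random lists of detected protein-coding genes, with 8. The number of varying genes lay between 5835 and 7350 under other scalings, filters and gene sets, and between 2142 and 5980 when a library was left out, the lowest without replicate 1. The coefficient of variation lay between 16.6% and 20.8%, and between 12.4% and 22.7% when a library was left out. Fewer libraries are compared in these fits. Lists with a spread above percentile 95 numbered 6 with total count scaling and 7 with length-bin scaling, and 5 to 8 when a library was left out. For Trbv segments, Cramér's V was 0.0705 with only segments of 10 or more counts, and 0.0778 to 0.0943 when a library was left out. For Trav segments it was 0.209, where counting error alone gives about 0.117. Trav7-2 had 0, 86 and 87 counts in libraries 1, 2 and 3, and Trav7d-2 had 89, 0 and 0. Reads that switch between segments of like sequence would raise Cramér's V without a change in segment use. How much of the Trav value comes from this was not tested. When a library was left out, the Trav value was 0.198 to 0.279, where counting error alone gives about 0.137 to 0.150. Each was past the chi-square threshold. Genes that differed between the gene tables numbered 3132 with a limit of 1.5-fold, which by construction takes more genes, 939 with a level of 5, and 1531 to 1544 when a library was left out. Agreement among fewer libraries is a looser rule, which favours a higher number. The median leading transcript share was 79.2% in the second transcript table, and 83.9% to 85.2% when a library was left out. Genes detected in every library have higher levels by construction, so a list reaches a lower percentile against random lists of them. The 20313 genes with posterior mean TPM were more than the 20217 with any expected count in library 3. That number therefore includes genes without an expected count there. The cause of the changes with posterior mean TPM and of the transcript share in the second table was not tested.

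Of 279 recomputed counts of detected list members, 23 moved by over 1.5 times. Of 100 recomputed TPM values of the always-named genes, 30 moved by over 1 SD. They were 19 with the second transcript table (median ratio to the main value 0.516) and 11 with posterior mean TPM (0.80). The 100 values include those with a library left out, of which 0 moved. Leaving out 1 of 3 libraries cannot move a mean by over 1 SD, so that 0 was fixed in advance and shows nothing about stability. In the second table Gm29013 takes 26.1%, 19.1% and 19.6% of all TPM, which by construction lowers the TPM of other genes, though by less than the ratio shows. The M4 table has no TPM, so it gave no value for detection or list level. Counts near 30 limit what the spread test can show. No paired analysis was possible because the libraries form 1 group.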

Other observations

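The tests in this part were chosen after the result was seen.

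Of the 10 neutrophil genes, 5 had 20 or more counts in library 1 and at most 5 in each of the other libraries, and 2 were highest in library 3. Besides Ngp, Ltf had 69, 5 and 1 counts in libraries 1, 2 and 3, S100a9 had 23, 0 and 4, S100a8 20, 0 and 1, and Camp, chosen after its values were seen, 26, 0 and 0. Mpo and Csf3r, chosen likewise, had 0, 0 and 16 counts and 5, 0 and 10 counts. Ly6g, with 1 count in library 1, Elane and Retnlg, with 0 in each library, make up the rest. Immunoglobulin heavy chain V segments differed between libraries 1 and 3 too, with a chi-square value per degree of freedom of 11.9 from 817 and 558 counts.

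Library 1 stood apart from the others over many genes. The length trend was not the whole difference. With each pair of libraries scaled within length bins, the coefficient of variation was 18.3% between libraries 1 and 2 and 18.2% between libraries 1 and 3, against 12.2% between libraries 2 and 3. The lower of the pairs with library 1 was 1.48 ± 0.0874 times the latter (SD over 20 resamples of genes), and 1.86 ± 0.0888 times with scaling within GC bins. Red cell RNA was not the whole cause either, since 2.79 times as many genes differed between libraries 1 and 3, whose globin counts differed 1.39-fold, as between libraries 2 and 3, whose globin counts differed 235-fold. RNA of other cell types, a difference in RNA fragmentation or in the cells taken for library 1 may remain, and none of these was tested. With 1 group, no biological explanation other than red cell RNA was tested.

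Genes with fewer counts in the M4 table tended to have a low coding share. Counting mainly over coding sequence is a candidate explanation, as the log2 ratio rose by 0.547 per log2 unit of coding share over 10046 genes. With even read coverage, a count over coding sequence alone would be proportional to the coding share, and the rise was weaker than that. Reads left out where genes overlap do not account for the relation, since among 6224 genes whose exons overlap no other gene the highest and lowest deciles of coding share still differed by 1.48 on the log2 scale. Nor does GC content, with a difference of 1.40 among genes of intermediate GC content. The largest differences lie beyond this trend. Klf13, with 12.8% of its exon bases coding, stood at -6.77, while the lower quartile in the decile of lowest coding share was -1.57. Gm11808 and Sap18b, with 76.2% and 65.4% coding, stood at -6.50 and -6.00, against the direction of the trend. A low coding share does not account for them. The other genes named with the largest differences had between 11.5% (Ube2h) and 25.5% (Lars2) coding. Changes between the annotation releases, the strand setting of the count and the handling of reads that match near-identical copies were not tested. The share of genes that overlap another gene was 37.0% among those lower in the M4 table and 38.0% among those that did not differ.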
